A study of Mus musculus with 22 samples.

How the data were processed

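Bulk RNA of mouse liver tumours and of adjacent liver was sequenced from polyadenylated transcripts in 20 libraries. The 5 + 5 libraries of the ethanol diet came from mice fed a Lieber-DeCarli liquid diet with 5% ethanol for 5 months, and the 4 + 4 libraries of the high-fat diet from mice fed for 4 months. The labels add 1 tumour and 1 adjacent library of a high-fat diet with 10% ethanol in the drinking water, for which no feeding time is given. Streptozotocin, a toxin of the insulin-producing beta cells, was given on postnatal day 2. A further 2 samples are single-cell libraries of nonparenchymal liver cells (all cells other than hepatocytes), purified on a Percoll density gradient and measured with a probe-based 10x Genomics assay.

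The deposited bulk table holds raw counts of reads per gene symbol with no normalization. Per the labels, the authors made it with bcl2fastq 2.20.0.422, STAR 2.6.0a and HTSeq 0.11.2 on GRCm38. For the libraries of the high-fat diet plus ethanol the labels name Cell Ranger and GRCm39 instead, which are tools of the single-cell data, so aligner and build are not stated for them. Their separate files of raw counts held the same values as the shared table, with 0 genes differing. In those files, 5 entries name no gene and took 28% and 29% of the counts, and they were left out. The table's 3 columns that match no labelled sample were not used here. The deposited single-cell matrix holds raw counts of unique molecular identifiers (UMIs) per gene and cell, made by the authors with Cell Ranger (version not given) on GRCm39. The deposited cell and gene name files hold other content, names only. Counts of the single-cell library of the high-fat diet plus ethanol were not analysed here.

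Totals ran from 14.13 to 21.64 M counts per bulk library (M, mega). The 10 most abundant genes took 10.42% to 21.88% of the counts and mitochondrially encoded transcripts 2.322% to 9.24%. Intervals and count floors cover counting error only.

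The 18 libraries of the ethanol and high-fat diets were fitted together as 4 groups in edgeR 4.0.16 (R 4.3.3), with TMM scaling, the filterByExpr filter (13686 of 22155 genes kept), glmQLFit and glmQLFTest. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The contrasts were tumour against adjacent liver within each diet, the difference between those changes, and ethanol against high-fat diet in adjacent liver and in tumours. Log2 changes are those of edgeR. Levels are CPM, counts scaled to a common library total, after TMM scaling, as mean ± SD over the libraries of a group. Positions are those of GENCODE M21 on GRCm38. The labels say that tumours were paired with adjacent tissue but not which samples form a pair, so the samples were compared as groups. The p-values measure the spread between these samples, and whether each came from a separate mouse is not stated. Diet, feeding time and the form of the diet go together and were not separable.

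In all, 39 gene lists were fixed, of which 36 had at least 5 tested members. Each was tested within each contrast with camera (limma 3.58.1, voom weights), at a preset correlation of 0.01 and again with an estimated correlation, and with fry. P-values were adjusted over the lists of a contrast. Members were also counted after an adjustment over the list alone.

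Genes to be named were fixed by a rule. Per contrast it took the 8 highest and 8 lowest log2 changes among called genes with at least 2 CPM on average and groups that did not overlap, leaving out predicted and pseudogene names. To these it added the 4 members of each list with the smallest p and 10 landmarks (Afp, Gpc3, Glul, Cyp2e1, Mki67, Alb, Trem2, Col1a1, Cd36 and Nqo1). For genes taken by size, the rule thus fixes that the groups do not overlap, except for the difference, where this was not required. Counts of libraries beyond the other group add no support for these genes. The 91 genes that the text names in these contrasts were picked from that set after their values were seen, leaving out genes for which a compared group held 0 to 3 counts, except where only levels or a bound are given. Groups, contrasts, tests, lists, the naming rule and all alternatives except 1 were chosen before the data were examined. The exception, chosen after, sums the counts of ethanol-diet tumour replicates 1 and 4.

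The libraries of the high-fat diet plus ethanol, 1 per tissue, were compared by log2 ratios of CPM by library totals, with a prior count of 2, over genes with a mean of at least 10 CPM. The 8 highest and 8 lowest ratios were named. List medians were placed among 10000 random lists matched in size and expression.

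Cells of the high-fat-diet single-cell library with at least 200 genes and at most 15% mitochondrial UMIs were kept. Doublets found by scrublet were removed. The rest were clustered in scanpy 1.11.5 (Python 3.11.15) from 2000 variable genes, 30 components and Leiden resolution 1. A cluster was named after the marker list with the highest mean log2 ratio, given at least 3 markers more than 2-fold up. It was left unnamed where its top 10 genes held more markers of another class or tissue. It was also left unnamed where its median UMIs were under 1/3 of that of all clustered cells and its top 10 genes held no marker of the list. Shares carry exact (Clopper-Pearson) 95% binomial intervals.

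The tests were checked on simulated data, negative binomial counts with known changes, drawn from the means, dispersions and depths of the 18 libraries. Apart from these changes, all groups were drawn with the same mean and dispersion per gene. Real tumours varied more between libraries than adjacent liver did, so the shares below may not hold for the real contrasts. Of the genes changed 4-fold, edgeR recovered 88% for ethanol-diet tumours, 84% for high-fat-diet tumours, 80% between diets in adjacent liver, 87% between diets in tumours and 66% for the difference of the tumour changes, with 0 of the wrong sign. At 2-fold the shares were 57.1%, 37%, 41.8%, 49% and 17.3%. In the same order, 2.04%, 6.2%, 1.63%, 3.57% and 7.78% of the calls fell on unchanged genes, over the intended 5% in high-fat-diet tumours and for the difference.

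The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, DESeq2 size factors, upper-quartile scaling, no filter and a filter of 1 CPM in 4 libraries. Others were a term for the letter in front of some sample numbers, a block of consecutive sample numbers, fits of only the compared groups and fits without each library. The high-fat plus ethanol ratios were repeated with a prior count of 0.5, with a minimum of 1 CPM and with TMM. Clusters were repeated at resolutions 0.5 and 2, with doublets kept, with at least 500 genes per cell and with 4000 variable genes.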

Results

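Gene expression was measured in liver tumours and adjacent liver of mice made prediabetic with streptozotocin, a toxin of insulin-producing beta cells, and fed ethanol, a high-fat diet or both. Bulk libraries came from the ethanol diet (5 tumours, 5 adjacent), the high-fat diet (4 tumours, 4 adjacent) and the high-fat diet plus ethanol (1 tumour, 1 adjacent). A single-cell library described nonparenchymal cells under the high-fat diet. Totals were 14.13 to 19.64 M counts (M, mega) in ethanol-diet tumours, 18.94 to 20.15 in ethanol-diet adjacent liver, 19.26 to 20.78 in high-fat-diet tumours and 19.6 to 21.27 in high-fat-diet adjacent liver. The high-fat plus ethanol libraries held 19.17 M (tumour) and 21.64 M (adjacent). Of the variance between the 18 libraries of the ethanol and high-fat diets, the first 3 principal components took 24.2%, 23.6% and 14.4%. Ethanol-diet tumour replicates 1 and 4 lay closest to each other among the tumours of that diet, with a chi-square per gene of 20.14 against 146.3 for the next pair.

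Ethanol-diet tumours were compared with adjacent liver to find the genes that change with tumour formation under ethanol. Genes of the pericentral zone, which Wnt signalling maintains around the central vein, fell in these tumours. Targets of NRF2, the regulator of the antioxidant response, rose together with cell cycle genes and several oncofetal markers. Most markers of resident macrophages fell, as did some drug-metabolizing enzymes and bile acid genes.

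In edgeR, 2086 of 13686 genes were called in ethanol-diet tumours, 1368 higher and 718 lower than in adjacent liver, and 735 and 383 of these changed more than 2-fold. The tumours and adjacent libraries did not overlap at 1629 genes (11.9%), where chance gives 0.794%. The count was 1300 without ethanol-diet adjacent replicate 5, 1344 without replicate 1 and 1345 without replicate 3 of that group, and 3548 with limma-voom and sample quality weights.

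Of 18 Wnt and pericentral genes, 15 fell and 3 did not pass, with a median log2 change of -2.51, and 17 fell when adjusted over the list alone. In limma, camera gave an adjusted p of 2.07e-15 with the preset correlation, and adjusted p = 0.188 with an estimated correlation. Glul, the glutamine synthetase of the hepatocytes next to the central vein (chromosome 1, 153899944 to 153909723), averaged 387 ± 218 CPM (SD, n = 5) in tumours and 2630 ± 1260 CPM (n = 5) in adjacent liver. Its log2 change was -2.77 (SE 0.407, edgeR adjusted p = 0.000647), and all 5 tumours lay below every adjacent library. The Wnt targets Sp5 (log2 -3.68) and Notum (-2.85) fell as well, also in 5 of 5 tumours, as did the pericentral enzymes Oat (-4.07) and Cyp2e1 (-3.75) and the glutamate transporter Slc1a2 (-4.24). Urea cycle and periportal genes fell less, with a median of -0.73, 4 of 14 lower (5 lower and 1 higher when adjusted over the list alone), and a limma camera adjusted p of 0.000516, and adjusted p = 0.296 with an estimated correlation.

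Of 26 NRF2 targets, 15 rose and 11 did not pass, 21 rose when adjusted over the list alone, and the median was 1.86. The limma camera adjusted p was 4.54e-10, and adjusted p = 0.232 with an estimated correlation. Slc7a11, the cystine importer that feeds glutathione synthesis, averaged 582 ± 563 CPM in tumours and 13 ± 10.1 CPM in adjacent liver (log2 5.49, SE 1, edgeR adjusted p = 0.0023, higher in 5 of 5). Nqo1 rose 9.28-fold (log2 3.21, SE 0.575, edgeR adjusted p = 0.00215, 5 of 5 tumours). Srxn1 (log2 3.10), Gclc (2.63) and Pgd (1.86) rose in all 5 tumours. Cell cycle genes rose at 23 of 31 members (25 adjusted over the list alone, median 1.5), with a limma camera adjusted p of 5.19e-12, and adjusted p = 0.28 with an estimated correlation. Among them, Mki67 rose from 9.16 ± 1.37 to 32.1 ± 9.45 CPM (log2 1.81), Foxm1 by 2.11 and Ccne1 by 2.23 on the log2 scale, each in 5 of 5 tumours. Of 15 p53 targets, 8 rose (10 adjusted over the list alone, median 0.77, limma camera adjusted p of 0.0013, and adjusted p = 0.366 with an estimated correlation). Cdkn1a (log2 2.02, 3 of 5 tumours) and Phlda3 (3.35, 4 of 5) were among them.

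Oncofetal markers, proteins of fetal liver that return in liver cancer, rose unevenly. Of 15, 8 rose and 7 did not pass, also when adjusted over the list alone (median 2.4, limma camera adjusted p of 0.024, and adjusted p = 0.438 with an estimated correlation). Gpc3 rose from 1.6 ± 0.891 to 233 ± 262 CPM (log2 7.18, SE 1.61, edgeR adjusted p = 0.00737), but only 3 of 5 tumours lay above every adjacent library, and replicates 1 and 4 held 0.41 and 0.0962 CPM. Afp rose in 4 of 5 tumours (log2 4.31, SE 0.869, edgeR adjusted p = 0.00413), and Golm1 in 5 of 5 (log2 2.93). With limma-voom and sample quality weights, adjusted p was 0.0754 for Afp, 0.791 for Gpc3, 0.119 for Phlda3 and 0.0913 for Cdkn1a. The lowest values over their alternatives were 1.88e-07, 9.13e-07, 1.48e-05 and 0.000559 in the same order, and these limma-voom values were the highest. Log2 changes in the limma-voom fit were 1.94 for Afp, 0.75 for Gpc3, 1.36 for Phlda3 and 0.98 for Cdkn1a.

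Of 13 Kupffer cell markers, genes of the resident liver macrophages, 8 fell and 5 did not pass (9 fell adjusted over the list alone, median -2.03). In limma, camera gave an adjusted p of 1.2e-07, and adjusted p = 0.232 with an estimated correlation. Clec4f averaged 53.5 ± 49.6 CPM in tumours and 339 ± 112 in adjacent liver (log2 -2.66, SE 0.667, edgeR adjusted p = 0.0134, 5 of 5), and Marco (-3.92) and Folr2 (-2.52) fell with it in 5 of 5. The markers of lipid-associated macrophages were not called as a list, and Trem2 averaged 3.42 CPM in both tissues. Col1a1 (log2 1.89) and Col4a1 (1.61) rose in 5 of 5 tumours and Sparc (2.21) in 4 of 5, while stellate cell and matrix genes as a list were not called (limma camera adjusted p of 0.0765, 5 of 25 higher, or 7 higher and 1 lower adjusted over the list alone).

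Drug metabolism genes fell at 10 of 24 members (12 adjusted over the list alone, median -0.87, limma camera adjusted p of 1.41e-08, and adjusted p = 0.261 with an estimated correlation). Bile acid genes fell at 7 of 20 and rose at 1 (9 and 1 adjusted over the list alone, median -0.80, limma camera adjusted p of 1.33e-06, and adjusted p = 0.232 with an estimated correlation). Female-biased liver genes fell at 6 of 13 and rose at 1 (7 and 1 adjusted over the list alone, median -1.97, limma camera adjusted p of 9.2e-07, and adjusted p = 0.188 with an estimated correlation). Cyp2c37 (log2 -4.33), Cyp7a1 (-3.72), the first enzyme of bile acid synthesis, and the female-biased A1bg (-5.39) fell in 5 of 5 tumours. Alb (log2 0.04, edgeR adjusted p = 0.967) was not called, nor was Cd36 (log2 0.88, edgeR adjusted p = 0.138, range over its alternatives 0.0124 to 0.494). Cd36 was called without ethanol-diet tumour replicate 2 (log2 1.14, adjusted p 0.0124) and with limma-voom and sample quality weights (0.98, 0.0236). The sperm gene Tekt5 rose from 0.51 ± 0.595 to 19.3 ± 14.9 CPM (log2 5.21, 5 of 5 tumours). A further 8 lists were called. ER stress genes were shifted up (4 of 16 higher). The lists shifted down were fatty acid synthesis (3 of 16 lower), fatty acid oxidation (1 of 23 lower, 1 higher), ethanol and aldehyde oxidation (2 of 16 lower), gluconeogenesis (4 of 12), hepatocyte identity (5 of 26), sinusoidal endothelial markers (2 of 14) and B and plasma cell markers (1 of 10). Most of their members did not pass, and the 8 lists had limma camera adjusted p from 2.55e-05 to 0.019, and adjusted p = 0.232 to 0.513 with an estimated correlation. The remaining 18 lists were not called. Acute phase proteins, interferon response, cholangiocyte markers and hypoxia genes among them had a median, mean or camera direction that differed in sign.

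High-fat-diet tumours were compared with adjacent liver to find the genes that change with tumour formation under high-fat feeding. Urea cycle and periportal genes fell steeply in these tumours, and the pericentral programme rose. Cell cycle genes rose as they did under ethanol. Resident macrophage markers, male-biased liver genes and gluconeogenesis genes fell.

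In edgeR, 1839 genes were called in high-fat-diet tumours, 1043 higher and 796 lower than in adjacent liver, and 625 and 549 of these changed more than 2-fold. The 4 tumours and 4 adjacent libraries did not overlap at 2642 genes (19.3%), where chance gives 2.86%. The count was 1024 without high-fat-diet adjacent replicate 1, 1217 without replicate 3 and 1168 without replicate 4 of that group, and 2963 with limma-voom and sample quality weights.

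Of 14 urea cycle and periportal genes, 13 fell, also when adjusted over the list alone, and the median log2 change was -3.94. The limma camera adjusted p was 4.72e-21, and adjusted p = 0.00867 with an estimated correlation. Gls2, the glutaminase of periportal hepatocytes (chromosome 10, 128194457 to 128210004), averaged 3.77 ± 2.05 CPM (SD, n = 4) in tumours and 317 ± 80.2 CPM (n = 4) in adjacent liver. Its log2 change was -6.39 (SE 0.526, edgeR adjusted p = 7.84e-06), with all 4 tumours below every adjacent library. The urea cycle enzymes Arg1 (38.3 ± 21 against 1540 ± 389 CPM, log2 -5.33) and Asl (-3.12) and the amino acid enzymes Hal (-5.60) and Sds (-6.35) fell in 4 of 4 tumours.

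Of 18 Wnt and pericentral genes, 13 rose and 5 did not pass (15 rose adjusted over the list alone), with a median log2 change of 2.15. In limma, camera gave an adjusted p of 1.33e-11, and adjusted p = 0.132 with an estimated correlation. Glul rose from 2640 ± 526 to 11800 ± 2510 CPM (log2 2.16, SE 0.444, edgeR adjusted p = 0.00455, 4 of 4 tumours). Axin2, a feedback inhibitor that Wnt signalling switches on, rose from 16.2 ± 1.83 to 121 ± 73.2 CPM (log2 2.90, SE 0.572, edgeR adjusted p = 0.00337, 4 of 4). The Wnt targets Nkd1 (log2 3.94), Sp5 (3.10) and Tcf7 (1.97) also rose in 4 of 4. Cyp2e1 was not called (log2 0.35, edgeR adjusted p = 0.814).

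Cell cycle genes rose at 25 of 31 members (28 adjusted over the list alone, median 1.74), with a limma camera adjusted p of 2.76e-18, and adjusted p = 0.132 with an estimated correlation. Mki67 rose from 18.3 ± 5.5 to 70.6 ± 45.6 CPM (log2 1.95, SE 0.395, edgeR adjusted p = 0.00404, 4 of 4), and the replication factor Mcm4 rose by 1.37 on the log2 scale in 4 of 4. NRF2 targets rose at 5 of 26 members (14 adjusted over the list alone, median 1.14, limma camera adjusted p of 6.34e-05, and adjusted p = 0.555 with an estimated correlation). Srxn1 rose in 4 of 4 tumours (log2 2.08), and Nqo1 did not pass (log2 1.71, edgeR adjusted p = 0.0745, 3 of 4 tumours), with a range of 0.0223 to 0.306 over its alternatives that includes 0.0235 with DESeq2, 0.0223 with limma-voom and sample quality weights, 0.0467 without high-fat-diet adjacent replicate 2 and 0.0415 without high-fat-diet tumour replicate 4. Oncofetal markers were not called as a list (limma camera adjusted p of 0.55, 2 of 15 higher and 1 lower, also adjusted over the list alone). Afp (log2 2.27, edgeR adjusted p = 0.105, range 0.021 to 0.299 over its alternatives, called with DESeq2 at 0.0308 and in edgeR on these 8 libraries alone at 0.021) and Gpc3 (log2 3.13, edgeR adjusted p = 0.194) did not pass. The protease gene Plat (log2 5.77), the oxidase gene Duox1 (5.99) with its partner Duoxa1 (5.72), Mmp24 (5.26), Col8a1 (4.88), Krt8 (1.87) and Col4a1 (1.58) rose in 4 of 4 tumours. Without high-fat-diet tumour replicate 1 the change of Duox1 was 3.68, still called.

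Kupffer cell markers fell at 11 of 13 members (13 adjusted over the list alone, median -2.19, limma camera adjusted p of 3.36e-09, and adjusted p = 0.132 with an estimated correlation). Clec4f (log2 -2.92), Cd163 (-4.41) and Marco (-4.66) fell in 4 of 4 tumours. Marco, called with an edgeR adjusted p of 0.0137, was not called without high-fat-diet adjacent replicate 3 (log2 -3.02, adjusted p 0.0682). With limma-voom and sample quality weights it was not called either (log2 -4.31, adjusted p 0.187), in a range of 0.000242 to 0.187 over its alternatives. Male-biased liver genes fell at 8 of 13 members, also adjusted over the list alone (median -2.21, limma camera adjusted p of 6.32e-06, and adjusted p = 0.132 with an estimated correlation). Mup7, a major urinary protein gene (chromosome 4, 60066469 to 60070475), averaged 2.5 ± 1.43 CPM in tumours and 469 ± 202 in adjacent liver (log2 -7.56, SE 0.93, edgeR adjusted p = 0.000119, 4 of 4). Mup11 (-7.12) and Selenbp2 (-2.60) fell with it, and the assignment of reads between near-identical Mup copies is uncertain. Igf1 fell by 3.70 on the log2 scale in 4 of 4 tumours. Gluconeogenesis genes fell at 8 of 12 members (9 adjusted over the list alone, median -0.97, limma camera adjusted p of 5.45e-07, and adjusted p = 0.132 with an estimated correlation). Cholesterol synthesis genes rose at 6 of 22 members (9 adjusted over the list alone, median 0.68, limma camera adjusted p of 0.00016, and adjusted p = 0.686 with an estimated correlation), among them Mvd (log2 1.53), while the lipid regulator Srebf1 fell (-1.10), both in 4 of 4. A further 6 lists were called. ER stress genes were shifted up (6 of 16 higher, 1 lower). Hepatocyte identity (9 of 26 lower), sinusoidal endothelial (5 of 14), acute phase (4 of 22), interferon (2 of 24 lower, 1 higher) and bile acid genes (3 of 20 lower) were shifted down, though most of their members did not pass. These 6 lists had limma camera adjusted p from 1.47e-07 to 0.042, and adjusted p = 0.132 to 0.75 with an estimated correlation. Alb, Cd36, Col1a1 and Trem2 were not called. Of the 22 lists not called, drug metabolism, ethanol and aldehyde oxidation, antigen presentation, neutrophil, stellate cell, hypoxia and red blood cell genes had a median, mean or camera direction that differed in sign.

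**Figure D1:**
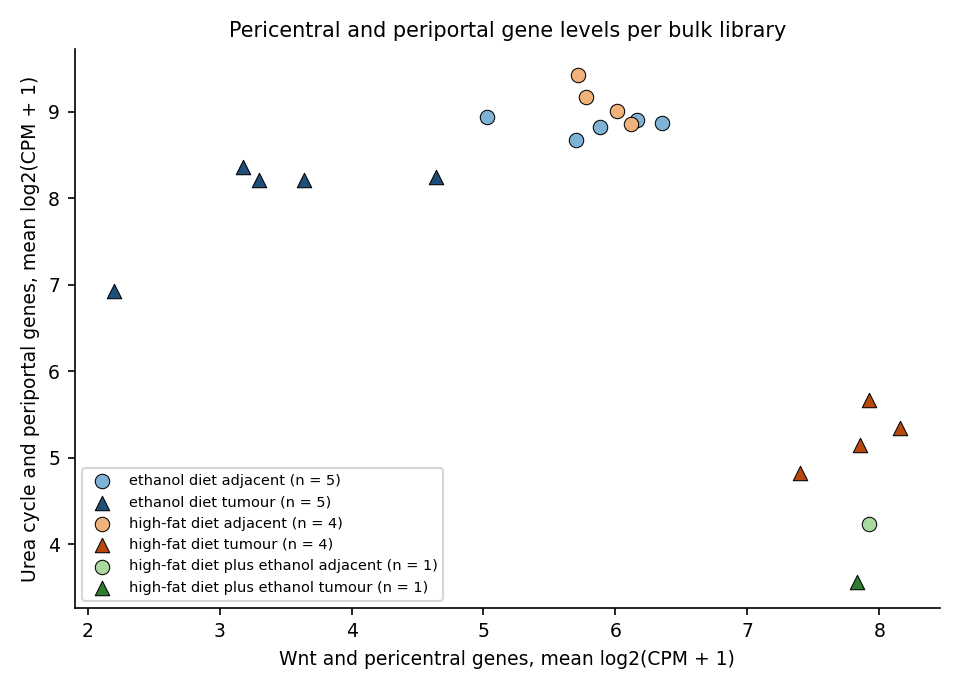
Mean log2(CPM + 1) of Wnt and pericentral genes (horizontal) against urea cycle and periportal genes (vertical), 1 point per bulk library, with triangles for tumours and circles for adjacent liver. Ethanol-diet tumours lie at 2.2 to 4.64 and high-fat-diet tumours at 7.4 to 8.16 on the horizontal axis, with all 9 adjacent libraries of these diets between them at 5.03 to 6.35.

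The tumour changes of both diets were set side by side, and their difference was tested gene by gene. Part of the response was shared, including the rise of cell cycle genes and the loss of resident macrophage markers. Pericentral genes moved in opposite directions, lower in ethanol-diet and higher in high-fat-diet tumours. Most periportal genes fell in high-fat-diet tumours, and a few of them in ethanol-diet tumours.

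Of 2086 and 1839 called genes, 671 changed in the same direction under both diets, 428 higher and 243 lower, where independent lists give 146. Both lists come from 1 fit with a shared spread per gene, which can also raise their overlap. Opposite directions occurred at 66 genes, 15 higher under ethanol and lower under high-fat feeding and 51 the reverse, where independent lists give 79.6 and 54.7. Across genes, which are not independent replicates, the log2 changes had a Spearman correlation of 0.461. The shared count was 415 without high-fat-diet adjacent replicate 1 and 1273 with limma-voom and sample quality weights. The test of the difference called 340 genes in edgeR, 160 higher and 180 lower under ethanol. That count was 212 without high-fat-diet adjacent replicate 1, 215 without replicate 4 of that group and 220 without ethanol-diet adjacent replicate 5, and was 676 with DESeq2 and 829 with limma-voom and sample quality weights.

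The difference of the tumour changes was negative for Wnt and pericentral genes, with a median of -4.48 and 16 of 18 members called (18 adjusted over the list alone). The limma camera adjusted p was 5.53e-39, and adjusted p = 0.00667 with an estimated correlation. Glul differed by -4.92 (SE 0.605, edgeR adjusted p = 0.000312), with the direction of its change seen in 5 of 5 ethanol-diet and 4 of 4 high-fat-diet tumours. Sp5 (-6.77), Nkd1 (-6.63) and Tcf7 (-2.92) differed likewise. Urea cycle and periportal genes differed the other way, with a median of 3.44 and 10 of 14 members called (11 adjusted over the list alone). In limma, camera gave an adjusted p of 2.1e-19, and adjusted p = 0.00667 with an estimated correlation. Gls2 differed by 5.58 (SE 0.6, edgeR adjusted p = 0.000109), and Hal (5.13), Arg1 (5.00) and Cyp2f2 (6.45) also did. Gldc, which is not in this list, differed by 6.95. Tiam2, which averaged 41.6 ± 13.3 CPM in ethanol-diet and 0.515 ± 0.483 CPM in high-fat-diet tumours against 8.27 and 11.2 CPM in adjacent liver, differed by 6.71. Acsm4 (-10.46), Duox1 (-8.93), Car4 (-7.59), Vldlr (-4.16) and Ldhb (-3.28) differed in the negative direction, with higher levels in high-fat-diet tumours. With limma-voom and sample quality weights, Acsm4 (adjusted p 0.214), Duox1 (0.114) and Car4 (0.119) were not called, against lowest values over their alternatives of 0.00013, 2.44e-05 and 6.3e-08.

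Among cell cycle genes, the difference was called for Ccne1 (1.98) and Mcm4 (-1.05, edgeR adjusted p = 0.0267). Mcm4 was not called without ethanol-diet adjacent replicates 2 (adjusted p 0.0574), 3 (0.0605) or 5 (0.0602), high-fat-diet tumour replicate 1 (0.0606) or high-fat-diet adjacent replicates 1 (0.0751) or 4 (0.0744), in a range of 0.00159 to 0.0796. The difference did not pass for Mki67 (log2 -0.14, edgeR adjusted p = 0.957), Nqo1 (1.51, 0.458), Afp (2.05, 0.504) or Gpc3 (4.05, 0.407), so a difference between the diets was not shown for these genes. As lists, drug metabolism (median -1.35), cholesterol synthesis (-0.42), fatty acid oxidation (-0.45), bile acid genes (-0.0351), NRF2 targets (0.62), glycolysis (0.55), acute phase proteins (1.57) and antigen presentation (0.53) were called, though only 0 to 3 members of each passed, with limma camera adjusted p from 5.22e-07 to 0.039, and adjusted p = 0.762 with an estimated correlation for each. The remaining 26 lists were not called, and in 4 of them (lipid droplet, insulin axis, hypoxia and mitochondrially encoded genes) median, mean and camera direction differed in sign.

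**Figure D2:**
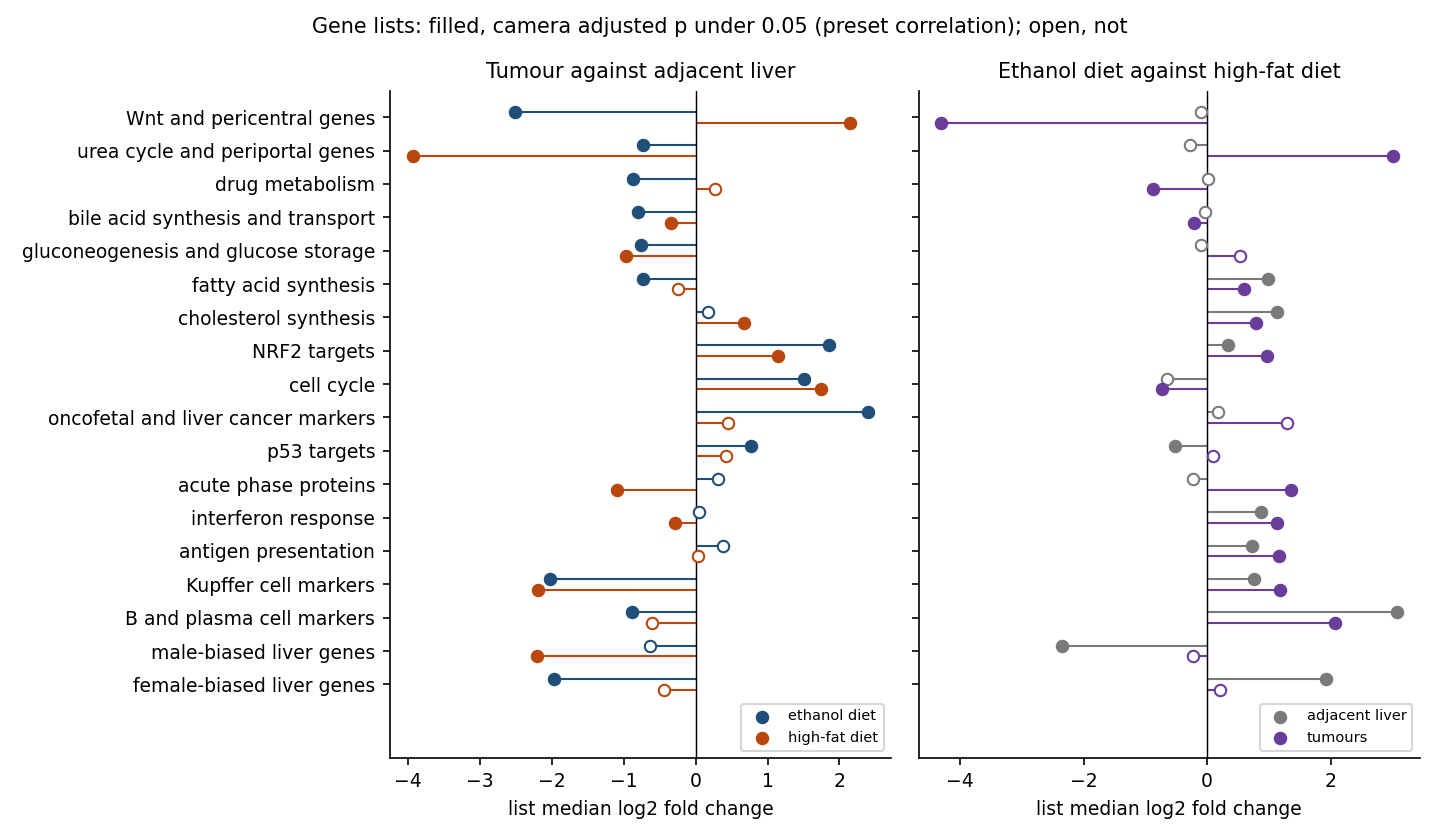
Median log2 change of 18 gene lists in tumours against adjacent liver (left) and in the ethanol diet against the high-fat diet (right). Filled points mark a limma camera adjusted p under 0.05 with the preset correlation, such as the Wnt and pericentral genes at -2.51 and 2.15 in tumours of the ethanol and high-fat diets.

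Adjacent liver was compared between the diets to find how ethanol and high-fat feeding differ outside tumours. No labelled sample came from a control diet, so a difference cannot be assigned to either diet alone. Most cholesterol synthesis genes and B and plasma cell markers were higher under the ethanol diet. Some interferon response genes and a few fatty acid synthesis genes were higher as well. Among sex-biased liver genes, several male-biased ones were lower and a few female-biased ones higher under ethanol. Feeding time (5 and 4 months) differs along with the diet, and cohort was not recorded per sample.

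In edgeR, 661 genes were called between the diets in adjacent liver, 290 higher and 371 lower under ethanol, and 179 and 156 of these differed more than 2-fold. The libraries of the diets did not overlap at 2813 genes (20.6%), where chance gives 1.59%. The count depended on single libraries and on the fit. Without ethanol-diet adjacent replicates 1, 2, 4 and 5 it was 418, 306, 307 and 390, and without high-fat-diet adjacent replicates 1, 3 and 4 it was 174, 341 and 184. High-fat-diet adjacent replicates 1 and 4 were the closest pair of their group (chi-square per gene 7.829, next pair 64.3). No fit joined them into 1 library, and if both came from 1 mouse, the p-values would be too small. The same holds for ethanol-diet adjacent replicates 2, 3 and 5 (chi-square per gene 10.98 to 15.5, group median 65.89). DESeq2 gave 1233 genes, edgeR on the adjacent libraries alone 2711 and limma-voom with sample quality weights 5775. The balance of directions also varied, with 344 higher and 317 lower under upper-quartile scaling and 265 and 394 with DESeq2 size factors. Limma-voom with sample quality weights gave 2960 higher and 2815 lower. The share of mitochondrial counts, a sign of RNA quality, did not overlap between the diets (4.505% to 6.591% under ethanol, 7.088% to 8.289% under high-fat feeding), and mitochondrially encoded transcripts as a list were not called (median -0.385, limma camera adjusted p of 0.0584).

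Cholesterol synthesis genes were higher at 13 of 22 members (21 adjusted over the list alone, median 1.13). The limma camera adjusted p was 2.68e-19, and adjusted p = 0.0989 with an estimated correlation. Mvd averaged 17.7 ± 4.08 CPM (n = 5) under ethanol and 3.86 ± 1.25 CPM (n = 4) under high-fat feeding (log2 2.19, SE 0.249, edgeR adjusted p = 8.85e-05, 5 of 5 above every high-fat library). Insig1 (1.91), Pmvk (1.5) and Fdft1 (1.29) were higher in 5 of 5. Fatty acid synthesis genes were higher at 4 of 16 members and lower at 1 (9 and 1 adjusted over the list alone, median 0.99, limma camera adjusted p of 1.26e-07, and adjusted p = 0.262 with an estimated correlation). Srebf1, a regulator of lipid synthesis (chromosome 11, 60199089 to 60222581), averaged 313 ± 70 against 88.1 ± 11.8 CPM (log2 1.83, SE 0.172, edgeR adjusted p = 2.19e-05, 5 of 5). Fasn (log2 2.49) and Pnpla3 (3.77) were higher in 5 of 5. Fasn, with an edgeR adjusted p of 0.0127, was not called without high-fat-diet adjacent replicate 1 (0.0645) or 4 (0.0614), in a range of 1.66e-07 to 0.0645 over its alternatives.

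Interferon response genes were higher at 9 of 24 members (19 adjusted over the list alone, median 0.87, limma camera adjusted p of 3.08e-12, and adjusted p = 0.0989 with an estimated correlation). Irf7, a driver of the interferon response, averaged 116 ± 30.7 against 56.2 ± 12.3 CPM (log2 1.05, SE 0.203, edgeR adjusted p = 0.00783, 5 of 5). Ifi44 (1.41), Oasl2 (1.21) and Ifit3 (1.47) were higher in 5 of 5. Antigen presentation genes were higher at 2 of 12 members (9 adjusted over the list alone, median 0.72, limma camera adjusted p of 6.18e-07, and adjusted p = 0.139 with an estimated correlation), among them H2-K1 (log2 0.78). B and plasma cell markers were higher at 9 of 10 members (10 adjusted over the list alone, median 3.07, limma camera adjusted p of 3.86e-09, and adjusted p = 0.139 with an estimated correlation). Jchain, which joins secreted antibodies, averaged 50.8 ± 35.4 against 1.97 ± 0.857 CPM (log2 4.67, SE 0.897, edgeR adjusted p = 0.00756, 5 of 5), and Fcmr (4.03) and Ms4a1 (3.45) were higher in 5 of 5. Ifit3 was not called without high-fat-diet adjacent replicate 1 (adjusted p 0.0719) or 4 (0.0525), in a range of 0.000165 to 0.0719. Ms4a1 was not called without replicate 4 (0.0525), in a range of 2.75e-05 to 0.0525. H2-K1 was not called without high-fat-diet adjacent replicates 1 (0.078), 2 (0.0533) or 4 (0.0848) or ethanol-diet adjacent replicate 4 (0.0546), in a range of 1.22e-05 to 0.0848.

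Male-biased liver genes were lower under ethanol at 7 of 13 members (10 adjusted over the list alone, median -2.34, limma camera adjusted p of 3.28e-09, and adjusted p = 0.0989 with an estimated correlation). Mup7 averaged 1.51 ± 0.955 CPM under ethanol and 469 ± 202 CPM under high-fat feeding (log2 -8.28, SE 0.873, edgeR adjusted p = 6.07e-05), with 5 of 5 below every high-fat library, and Mup11 (-8.13), Selenbp2 (-2.85) and Susd4 (-3.81) were lower too. Female-biased genes were higher at 3 of 13 members (5 adjusted over the list alone, median 1.92, limma camera adjusted p of 1.57e-06, and adjusted p = 0.0989 with an estimated correlation). Slc22a26, a transporter gene of this list, was higher in 5 of 5 (log2 4.03, edgeR adjusted p = 0.0143), but was not called without high-fat-diet adjacent replicate 1 (0.0702) or 4 (0.0669), in a range of 4.62e-06 to 0.0702. The interferon-inducible Ifi202b (chromosome 1, 173962568 to 173982744) averaged 15.4 CPM under ethanol and had 0 counts in all 4 high-fat-diet adjacent libraries. It was at least 387-fold higher against a floor of 3 counts over that group (0.0398 CPM). Ifi44l averaged 20.1 ± 2.39 against 0.0135 ± 0.027 CPM, and Cebpe 0.0206 ± 0.0283 against 5.83 ± 0.587 CPM. Nlrp12 was lower under ethanol (2.23 ± 1.18 against 102 ± 19.7 CPM, log2 -5.52). Another 6 lists were called, though few or none of their members passed. T and NK cell markers (1 of 20 higher), Kupffer cell markers (0 of 13 called), NRF2 targets (0 of 26) and inflammatory genes (0 of 20) were shifted up. Insulin axis genes (1 of 15 lower) and p53 targets (1 of 15 lower, 1 higher) were shifted down. The 6 lists had limma camera adjusted p from 0.00109 to 0.0341, and adjusted p = 0.423 to 0.911 with an estimated correlation. Wnt and pericentral genes (0 of 18 called, median -0.10, limma camera adjusted p of 0.925) and periportal genes (1 of 14 lower, 0.254) were not called, and Glul (2630 against 2640 CPM), Cyp2e1 and Trem2 did not pass. Trem2 (log2 1.22, edgeR adjusted p = 0.217) was called with limma-voom and sample quality weights (0.00416) and in edgeR on the adjacent libraries alone (0.0403), in a range of 0.00416 to 0.449. Of the 23 lists not called, drug metabolism, lipid droplet and capillary genes had a median, mean or camera direction that differed in sign.

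**Figure D3:**
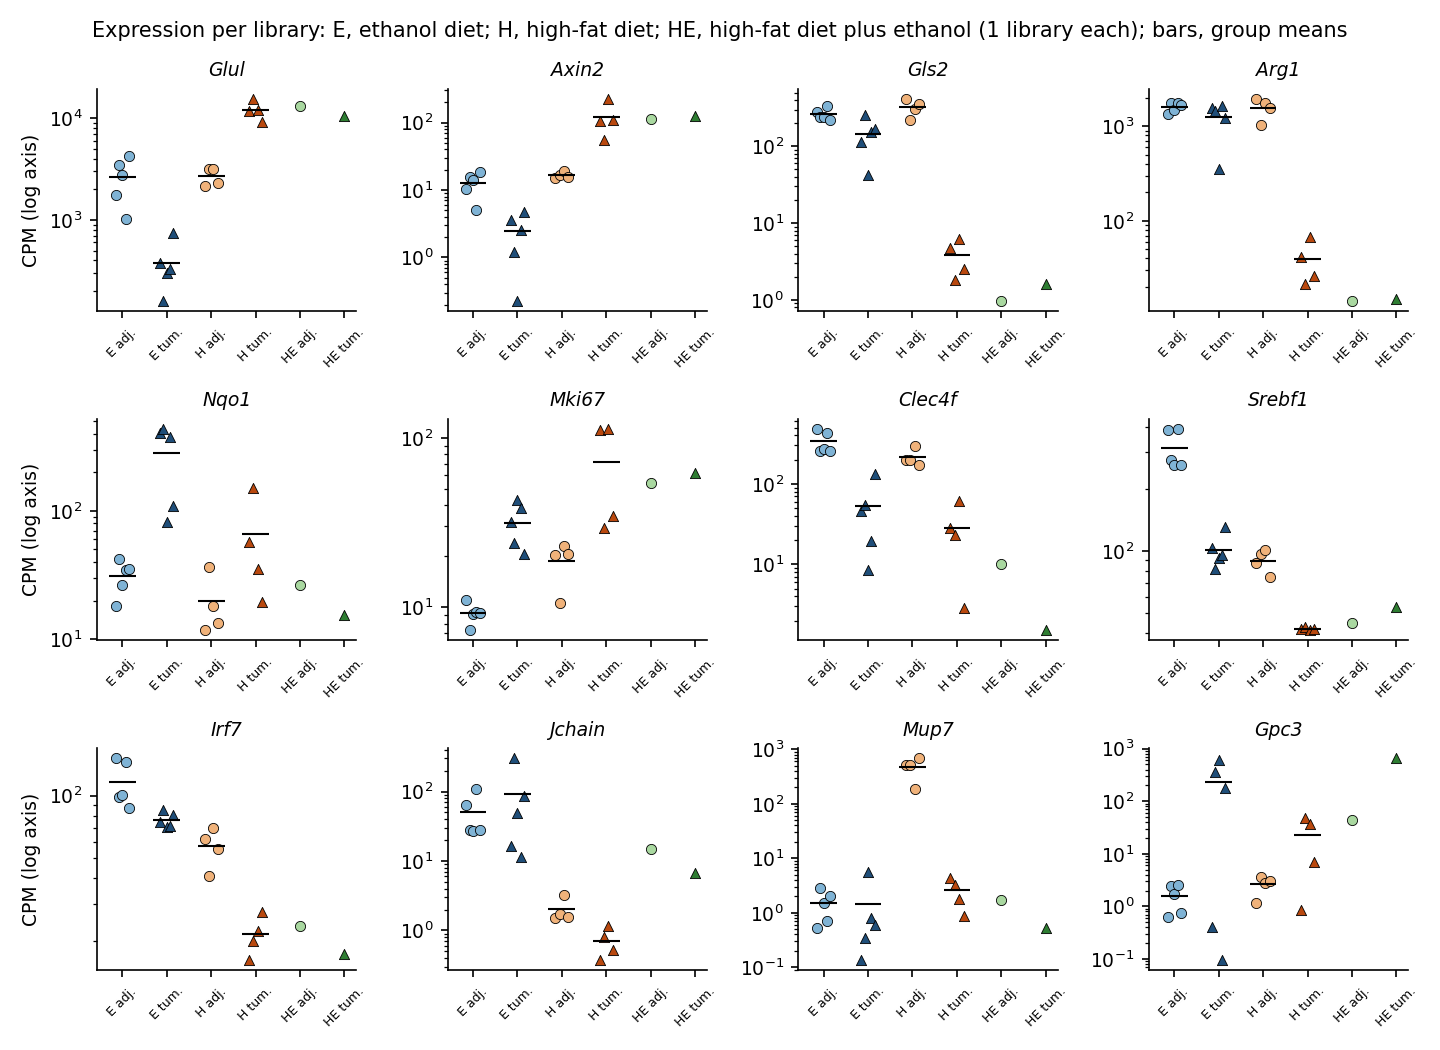
Expression of 12 genes in each bulk library, as CPM on a log axis, with group means as bars for the ethanol (E) and high-fat (H) diets. Glul averaged 387 CPM in ethanol-diet and 11800 CPM in high-fat-diet tumours, while adjacent liver of these diets averaged 2630 and 2640 CPM.

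Tumours were compared between the diets to find how ethanol-diet and high-fat-diet tumours differ from each other. Pericentral genes were lower and periportal genes higher in ethanol-diet tumours. Most interferon, antigen presentation and B and plasma cell genes were higher in ethanol-diet tumours. Cell cycle genes were lower in ethanol-diet tumours, at a few members.

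In edgeR, 2787 genes were called between tumours of the diets, 1437 higher and 1350 lower under ethanol, and 903 and 557 of these differed more than 2-fold. The tumours did not overlap at 1609 genes (11.8%), where chance gives 1.59%. Of the called genes, 337 also differed in the same direction in adjacent liver, where independent lists give 67 (the shared fit can raise this). The count was 1722 without high-fat-diet tumour replicate 1, and 767 (302 higher, 465 lower) in edgeR on the tumour libraries alone. Its balance depended on the scaling, with 1725 higher and 1146 lower under upper-quartile scaling and 1332 and 1503 with DESeq2 size factors.

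All 18 Wnt and pericentral genes were lower in ethanol-diet tumours, also adjusted over the list alone (median -4.3, limma camera adjusted p of 3.32e-23, and adjusted p = 0.0976 with an estimated correlation). Glul differed by -4.93 (SE 0.457, edgeR adjusted p = 3.57e-06, 5 of 5 below every high-fat-diet tumour), and Sp5 (-6.96), the ammonium transporter gene Rhbg (-5.83), Znrf3 (-2.68), Slc1a2 (-7.26) and Cyp2e1 (-4.12) were lower in 5 of 5. Periportal genes were higher at 10 of 14 members (11 adjusted over the list alone, median 3.01, limma camera adjusted p of 4.14e-10, and adjusted p = 0.0976 with an estimated correlation), with Arg1 at 1270 ± 531 against 38.3 ± 21 CPM (log2 5.05, SE 0.466, edgeR adjusted p = 3.46e-06, 5 of 5), Hal (5.67) and Gls2 (5.30).

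Interferon response genes were higher at 17 of 24 members and lower at 1 (18 and 1 adjusted over the list alone, median 1.13, limma camera adjusted p of 3.18e-10, and adjusted p = 0.153 with an estimated correlation). Irf7 averaged 77.9 ± 7.45 against 21 ± 4.86 CPM (log2 1.89, SE 0.21, edgeR adjusted p = 1.94e-05, 5 of 5), and Mx1 (2.27) and Ifi44 (2.22) were higher in 5 of 5. Antigen presentation genes were higher at 11 of 12 members (12 adjusted over the list alone, median 1.17, limma camera adjusted p of 1.43e-07, and adjusted p = 0.153 with an estimated correlation), including H2-K1 (1.14), Tap1 (1.31) and H2-Aa (1.90), each in 5 of 5. B and plasma cell markers were higher at 7 of 10 members (9 adjusted over the list alone, median 2.07, limma camera adjusted p of 0.000106, and adjusted p = 0.594 with an estimated correlation). Jchain averaged 95.5 ± 125 against 0.705 ± 0.349 CPM (log2 7.05, edgeR adjusted p = 0.000207, 5 of 5), and Mzb1 was also higher (3.60). Adjusted p reached 0.0672 for Jchain with limma-voom and sample quality weights (lowest of its alternatives 4.35e-20) and 0.064 for H2-Aa in edgeR on the tumour libraries alone (lowest 4.31e-05).

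NRF2 targets were higher at 10 of 26 members, also adjusted over the list alone (median 0.97, limma camera adjusted p of 0.000341, and adjusted p = 0.594 with an estimated correlation). G6pdx (2.10) and Pgd (1.58), of the pentose phosphate pathway, and the cholesterol regulator Insig1 (1.59) were higher in 5 of 5. Nqo1 (log2 2.18, edgeR adjusted p = 0.0168, 3 of 5 tumours) was not called without high-fat-diet tumour replicate 1 (0.0541) or 3 (0.0505) or in edgeR on the tumour libraries alone (0.103), in a range of 0.00106 to 0.103. Cell cycle genes were lower at 8 of 31 members and higher at 1, also adjusted over the list alone (median -0.73, limma camera adjusted p of 8.36e-05, and adjusted p = 0.597 with an estimated correlation). Mki67 (log2 -1.14, edgeR adjusted p = 0.034) and Top2a (-1.03, 0.0157) were lower, with 2 of 5 tumours below every high-fat-diet tumour for each. Mki67 was not called without ethanol-diet tumour replicates 1 (0.0571), 2 (0.067) or 5 (0.0672) or high-fat-diet tumour replicates 1 (0.134) or 3 (0.116), or in edgeR on the tumour libraries alone (0.132) or limma-voom with sample quality weights (0.0592), in a range of 0.00716 to 0.134. Top2a was not called without high-fat-diet tumour replicates 1 (0.0516) or 3 (0.0596), or in the fit of the tumours alone (0.0895), in a range of 0.00239 to 0.0895. Duox1 (-8.85) and Car4 (-8.34) were lower, and the chemokine gene Ccl20 (7.20), Spink1 (8.66) and Gapdh (1.62) higher, each in 5 of 5 ethanol-diet tumours. Spink1 reached an adjusted p of 0.218 with limma-voom and sample quality weights (lowest of its alternatives 5.44e-09). Afp (log2 1.29, edgeR adjusted p = 0.268) and Gpc3 (log2 3.35, edgeR adjusted p = 0.107) did not pass. Gpc3 was called without ethanol-diet tumour replicate 4 (0.0443) and with DESeq2 (0.0492), in a range of 0.0443 to 0.505, and its log2 difference was -1.83 with limma-voom and sample quality weights. A further 11 lists were called, at limma camera adjusted p from 7.49e-06 to 0.0285, and adjusted p = 0.544 to 0.63 with an estimated correlation. Shifted up were cholesterol synthesis (10 of 22 higher), fatty acid synthesis (4 of 16), acute phase (6 of 22), inflammatory (5 of 20), Kupffer cell (3 of 13), lipid-associated macrophage (3 of 14) and T and NK cell genes (4 of 20 higher, 1 lower). Shifted down were drug metabolism (10 of 24 lower, 1 higher), fatty acid oxidation (7 of 23 lower), bile acid (5 of 20 lower, 1 higher) and insulin axis genes (3 of 15 lower, 1 higher). Of the 18 lists not called, lipid droplet, neutrophil, capillary, cholangiocyte and ER stress genes had a median, mean or camera direction that differed in sign.

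The high-fat diet plus ethanol was represented by 1 tumour library and the library labelled adjacent, which were compared as values without a test. The oncofetal genes Afp and Gpc3 were far higher in the tumour library. Some genes of gluconeogenesis, drug metabolism and bile acids were lower in it. Both libraries held high pericentral and low periportal expression, like high-fat-diet tumours.

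Of 8668 genes with a mean of at least 10 CPM, 400 differed more than 2-fold, 192 higher and 208 lower in the tumour library. The 8 highest ratios were those of Serpina12, Afp, Kif5c, Gnal, Gpc3, Cyp3a16, Cyp2a4 and Scd1. Afp stood at 3060 against 172 CPM (log2 4.16) and Gpc3 at 706 against 46 CPM (3.94). The 8 lowest were Pck1, Cyp4a12a, Hsd17b6, Gnai1, Cyp4a12b, B3galt1, Apoa5 and Bhmt. Pck1, the gatekeeping enzyme of gluconeogenesis, stood at 122 against 904 CPM (log2 -2.89). As a description, 25 of 33 lists had a median outside the central 95% of matched random lists, a range that does not allow for list members moving together. Few members of most lists differed more than 2-fold. Oncofetal markers (median 1.2), neutrophil markers (2.05), glycolysis (0.68), hypoxia (0.66), p53 targets (0.44), fatty acid synthesis (0.43) and cholesterol synthesis (0.26) lay above it. Male-biased genes (-1.71), female-biased genes (-1.33), periportal genes (-0.81), sinusoidal endothelial markers (-0.80), bile acid genes (-0.78), drug metabolism (-0.77), stellate cell genes (-0.76) and gluconeogenesis (-0.43) lay below. Mitochondrially encoded transcripts, a sign of RNA quality, lay below it too (-0.76), with 2.322% of counts in the tumour library and 3.933% in the library labelled adjacent. Acute phase proteins lay inside it (percentile 51.6), and Alb stood at 65100 against 38800 CPM (log2 0.75). Wnt and pericentral genes (0.0637, percentile 68.4) and cell cycle genes (0.188, percentile 96.3) lay inside it. Across 8653 genes, the ratios had a Spearman correlation of 0.359 with the ethanol-diet and 0.214 with the high-fat-diet tumour changes.

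Among the groups of the other diets, the library labelled adjacent resembled high-fat-diet tumours most. Its Spearman correlation across genes was 0.971 with the mean of high-fat-diet tumours, 0.931 with high-fat-diet adjacent liver, 0.931 with ethanol-diet tumours and 0.916 with ethanol-diet adjacent liver, and 0.979 with the tumour library of its diet. The tumour library was likewise closest to high-fat-diet tumours (0.94). The mean log2(CPM + 1) of Wnt and pericentral genes was 7.92 in the library labelled adjacent and 7.83 in the tumour library, and that of periportal genes 4.24 and 3.56.

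Nonparenchymal cells under the high-fat diet were described from 1 single-cell library. Immune cells made up most of it, led by monocytes, innate lymphoid cells and T cells. Kupffer and endothelial cells were few among these cells, which had been purified on a Percoll gradient. Cell classes are named for the marker genes they resemble.

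The library held 7451 cells and 67.23 M UMIs, with a median of 5038 UMIs per cell. After filtering and the removal of 101 doublets (1.37%), 7271 cells formed 28 clusters and 16 classes. Monocyte-like cells made up 25.7% (95% exact interval 24.7% to 26.8%), natural killer or innate lymphoid cell-like cells 15.9% (15.1% to 16.8%), T cell-like cells 12.5% (11.7% to 13.3%) and neutrophil-like cells 8.21% (7.59% to 8.87%). B cell-like cells made up 5.96% (5.42% to 6.52%) and plasma cell-like cells 5.47% (4.96% to 6.02%). Dendritic cell-like cells of type 1 made up 5.32% (4.82% to 5.86%), those of type 2 5.25% (4.75% to 5.79%), plasmacytoid ones 0.976% (0.763% to 1.23%) and migratory ones 0.413% (0.279% to 0.588%). Monocyte-derived macrophage-like cells made up 4.58% (4.11% to 5.09%), Kupffer cell-like cells 1.36% (1.11% to 1.66%), basophil or mast cell-like cells 1.53% (1.26% to 1.84%), cholangiocyte-like cells 0.949% (0.739% to 1.2%) and sinusoidal endothelial cell-like cells 0.715% (0.535% to 0.937%). Hepatocyte-like cells made up 2.71% (2.35% to 3.11%), with a median of 84224 UMIs. The basophil or mast cell-like cluster was also led by Mpo, Ctsg and Elane, genes of granulocyte precursors. The 2 unnamed clusters held 2.42% of cells (2.08% to 2.8%), and 1 of them, 111 cells, was led by pancreatic enzyme genes such as Ctrb1 and Cpb1. The other, 65 cells with a median of 849 UMIs, was led by mitochondrially encoded genes such as mt-Atp6 and mt-Co1. The classes depended on the clustering. Type 2 dendritic cell-like cells were 0% and migratory ones 9.96% at resolution 0.5, and macrophage-like cells ranged from 0% to 9.33% over the alternatives.

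Marker genes of the bulk comparisons were looked up in these classes, where RNA set free by other cells adds a background. Clec4f, Jchain and Trem2 are among the markers that named the Kupffer cell-like, plasma cell-like and macrophage-like classes. Their high levels there are therefore partly fixed by the naming and are no separate support for it. Clec4f stood at 2374 CPM of UMIs in Kupffer cell-like cells, with a UMI in 98% of 99 cells (median 7463 UMIs), against 0.962% of 1871 monocyte-like cells (median 5771 UMIs). Jchain stood at 26640 CPM in plasma cell-like cells, with a UMI in 98.7% of cells, and a UMI was also found in 18% of monocyte-like cells, which make no antibody. Trem2 stood at 25.8 CPM in macrophage-like cells, with a UMI in 11.1% of 333 cells, against 7.27% of 1871 monocyte-like cells (12.8 CPM) and 0.11% of 907 T cell-like cells. Gpc3 had 17 UMIs and Afp 78 UMIs in all 7271 cells. Ifi202b had 2 UMIs and Ifi44l 1 UMI of 65932369 in all cells.

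**Figure D4:**
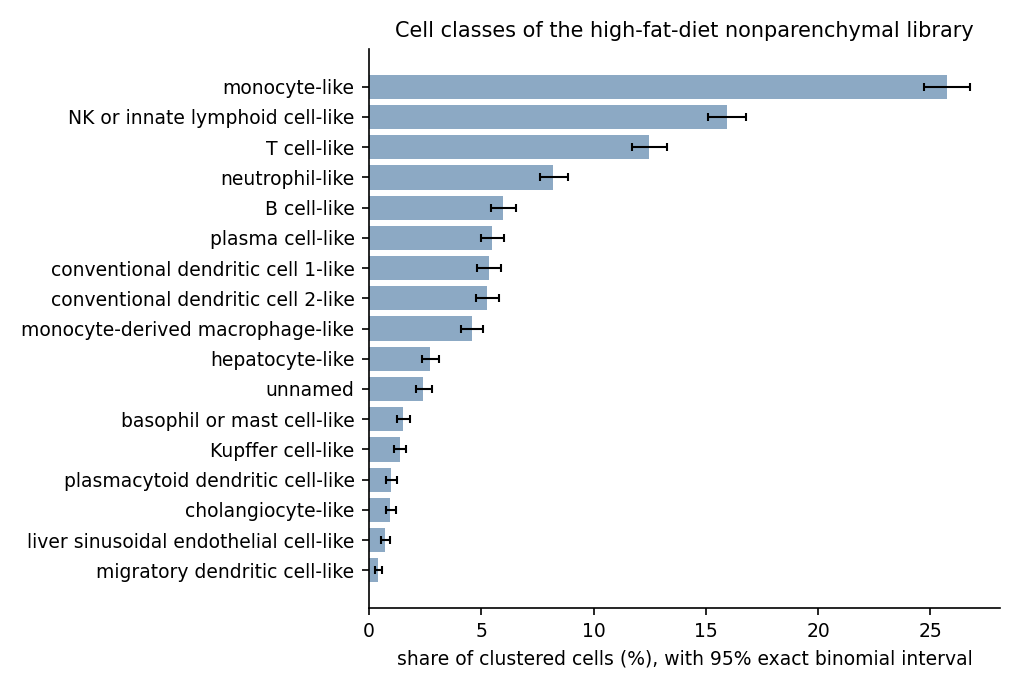
Share of 7271 clustered cells in each class of the high-fat-diet nonparenchymal library, as bars in percent with exact 95% binomial intervals. Monocyte-like cells hold 25.7% of cells and Kupffer cell-like cells 1.36%.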

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

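Of the tests in this part, the regroupings of libraries were planned ahead, and the other 7 and the sum of replicates 1 and 4 were chosen only after the results were seen.

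A library far from the others of its group was searched for in the totals and in 17 genes, with a ratio of the gap to the group's range. Of 80 such tests, 8 passed the limit, where chance gives about 5%. Ethanol-diet tumour replicate 1 held fewer counts (14.1 M, ratio 0.751) than the others. Cyp2e1 stood at 1980 CPM in ethanol-diet tumour replicate 5 and at 76.1 to 333 CPM in the other 4 (ratio 0.865). Slc7a11 stood at 196 CPM in high-fat-diet tumour replicate 2 and at 11.6 to 33.2 CPM elsewhere in the group (0.883). Afp stood apart in ethanol-diet tumour replicate 2 (198 CPM, ratio 0.718) and in high-fat-diet tumour replicate 3 (58.7 CPM, 0.838). Jchain stood apart in ethanol-diet tumour replicate 2 (303 CPM, 0.748) and in high-fat-diet adjacent replicate 3 (3.27 CPM, 0.881). Mup7 stood at 5.49 CPM in ethanol-diet tumour replicate 3 and at 0.137 to 0.817 CPM in the others (0.873).

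The tumour change differed between the diets at 340 genes. The log2 differences of pericentral genes were -6.77 for Sp5, -4.92 for Glul, -6.63 for Nkd1, -2.92 for Tcf7 and -4.1 for Cyp2e1. Cyp2e1 (edgeR adjusted p = 0.043) stayed called without ethanol-diet tumour replicate 3 or 5, ethanol-diet adjacent replicate 4 or high-fat-diet tumour replicate 4, and was lost without any 1 of the other 14 libraries (adjusted p from 0.0541 without high-fat-diet tumour replicate 3 to 0.0986 without high-fat-diet adjacent replicate 4), with a lowest value of 9.57e-05 over its alternatives. It was also lost with no filter beyond 1 count (0.0509), with the title prefix as a term (0.0515) and with ethanol-diet tumour replicates 1 and 4 summed (0.0636). Periportal genes differed by 5.58 for Gls2, 5.13 for Hal, 5 for Arg1 and 6.45 for Cyp2f2. Other genes differed by 6.95 for Gldc, 6.71 for Tiam2, -8.93 for Duox1, -10.5 for Acsm4, -7.59 for Car4, 1.98 for Ccne1, -1.05 for Mcm4, -4.16 for Vldlr and -3.28 for Ldhb. List medians differed by -4.48 for Wnt and pericentral genes, 3.44 for periportal genes, -1.35 for drug metabolism, 0.623 for NRF2 targets, -0.422 for cholesterol synthesis, -0.451 for fatty acid oxidation, -0.0351 for bile acid genes, 0.552 for glycolysis, 1.57 for acute phase proteins and 0.534 for antigen presentation.

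Libraries were also regrouped in other ways, and the real grouping ranked 1 in each set of splits. It called 2086 genes in ethanol-diet tumours (highest other of 100 splits 1128), 1839 in high-fat-diet tumours (3 of 35), 340 for the difference of the tumour changes (110 of 100), 661 in adjacent liver between the diets (9 of 100) and 2787 in tumours between the diets (1828 of 100). A grouping by accident is therefore unlikely to give counts of this size.

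The opposite change of pericentral genes in tumours was weighed first. A difference between the adjacent pieces is unlikely to make it, since the mean Wnt and pericentral level of adjacent liver differed by -0.0815 (95% interval -0.722 to 0.559) against a difference of the tumour changes of -4.36. A single library or the similar replicates 1 and 4 are unlikely to make it either, since the list median stayed at -4.2 or further from 0 without each library and was -4.45 with these replicates summed. The difference thus lay in the tumour libraries, but feeding time and the form of the diet go together with the diet and were not told apart. Cohort was not recorded per sample. Ethanol-diet tumours might arise without active Wnt signalling and high-fat-diet tumours with it, as with a mutation that activates beta-catenin, which was not tested here.

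The tumour-like profile of the library labelled adjacent under high-fat diet plus ethanol was weighed second. A swap of the labels is unlikely to explain it, because the library labelled tumour also lay outside all 9 adjacent libraries at 28 of 32 zonal genes, against 29 for the library labelled adjacent. Part of the sampled tumour inside the adjacent piece was not excluded. Afp (161 against 2810 CPM) allows at most 5.72% of such tissue only if its level is even across the tumour, which was not measured. With that share taken out, 31 of the genes lay outside, 2 more than before. The 2 libraries had similar zonal levels, so taking out a share could hardly bring the genes back, and the test decides nothing. A part of the sampled tumour with less Afp, tissue of another tumour or an effect of the combined diet on the whole liver could each give this profile. With 1 pair these were not told apart.

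Genes on under 1 diet and off under the other in both tissues were weighed last. Ifi202b, Ifi44l, Gm5678, Myom2 and Trim34b were on under ethanol and Cebpe and C1s2 under high-fat feeding, names chosen after their values were seen. A test of library depth found 0 of the 7 genes with counts in the range that depth allows, but the rule that picked the genes already fixes this, so it decides nothing. Both libraries of the high-fat diet plus ethanol lay on the ethanol side at 0 of the genes, which goes against ethanol exposure, but they are 1 pair on another diet and ethanol dose. Genes separating the diets had 26 neighbouring pairs on a chromosome (permuted mean 8.01, highest 25, permutation p = 1e-04, the smallest possible). This goes with a genetic background that differs between the mice of the 2 diets, but neighbouring genes that the diet regulates together would also raise the count. Neither cohort nor strain was recorded per sample, so background and diet cannot be told apart and any contrast between the diets could carry either.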

How the results depend on the processing

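Of the alternatives in this part, the sum of ethanol-diet tumour replicates 1 and 4 was chosen only after the data were seen.

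With DESeq2, the genes whose tumour change differs between the diets numbered 676 and those differing in adjacent liver 1233. Limma-voom with sample quality weights gave 3548 genes in ethanol-diet tumours, 2963 in high-fat-diet tumours, 1273 in tumours of both, 829 for the difference of the tumour changes and 5775 in adjacent liver. For both tools the cause was not tested. In fits of only the 2 groups compared, 2711 genes differed in adjacent liver and 767 in tumours, which kept 27.5% of the tumour calls. Libraries differed more within tumour groups (median chi-square per gene 281.1 under ethanol, 176.2 under high-fat feeding) than within adjacent groups (65.89 and 73.54). The fit of 4 groups shares its spread between them, so it may call too few genes in adjacent liver and too many between tumours. With an estimated correlation, 3 lists were called of 73 with the preset, the periportal list in high-fat-diet tumours and the pericentral and periportal lists for the difference. Fry called 14 lists in ethanol-diet tumours, 7 in high-fat-diet tumours, 7 between diets in adjacent liver and 14 between tumours. The preset camera had called 18, 14, 13 and 18. For the difference, fry called only the pericentral and periportal lists, against 10 with the preset. For the high-fat diet plus ethanol, 978 genes differed more than 2-fold at a mean of at least 1 CPM, a minimum that adds genes with lower counts.

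Counts with each library left out ran from 1300 (ethanol-diet adjacent replicate 5) to 2566 (ethanol-diet tumour replicate 5) in ethanol-diet tumours. They ran from 1024 (high-fat-diet adjacent replicate 1) to 2223 (high-fat-diet tumour replicate 2) in high-fat-diet tumours, and from 415 to 828 for both. The range was 212 to 486 for the difference, 174 to 618 in adjacent liver and 1722 to 3405 between tumours, with fewer samples in each.

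The labels call tumour and adjacent samples paired without saying which belong together. Neighbouring title numbers gave correlations of -0.2 to 0.045 under ethanol and 0.097 to 0.44 under high-fat feeding, where 3 of 4 tumours but 0 of 5 under ethanol correlated best with their own number, so no pairing was used. With it as a block, 1481, 1346 and 229 genes were called in ethanol-diet tumours, high-fat-diet tumours and the difference. Afp (adjusted p 0.0674) and Gpc3 (0.142) in ethanol-diet tumours and Acsm4 (0.0705), Car4 (0.0517) and Mcm4 (0.0796) for the difference were not called under this edgeR block. With replicates 1 and 4 summed, 1746 genes were called in ethanol-diet tumours and 318 for the difference.

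Other alternatives kept each count within 1.5 times its value, and no called gene that is named reversed its direction. Of those called, 26 of 30 in ethanol-diet tumours, 28 of 29 in high-fat-diet tumours, 13 of 18 for the difference, 19 of 24 in adjacent liver and 22 of 28 between tumours stayed called under all alternatives. In simulated counts, 2-fold changes of the difference were found at 17.3%, so genes not called may still differ.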

Other observations

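Of the values in this part, Ide and the rule for genes on under 1 diet were chosen only after the data were seen, and the similarity of libraries was read without a prediction.

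A gene counted as on under 1 diet and off under the other when the off diet stayed under 0.5 CPM in every library and the on diet stood at least 4 times higher, and over 0.5 CPM itself. The last condition was added after the data were seen, and 10 genes instead of 7 passed without it. Ide, which encodes an insulin-degrading enzyme, ran from 106 to 159 CPM in all ethanol-diet libraries and from 261 to 593 CPM in all high-fat-diet libraries, and stood at 254 and 266 CPM in the tumour and adjacent libraries of the high-fat diet plus ethanol.

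Besides ethanol-diet tumour replicates 1 and 4, the closest libraries within a group were ethanol-diet adjacent replicates 2, 3 and 5 and high-fat-diet adjacent replicates 1 and 4. Chi-square per gene was 10.98 for 3 and 5, 11.94 for 2 and 5 and 15.5 for 2 and 3 in ethanol-diet adjacent liver (median of the group 65.89). It was 7.829 for the high-fat-diet pair (median 73.54). No fit joined any of these adjacent libraries. If the close libraries of a group came from 1 mouse, p-values of contrasts with that adjacent group would be too small.

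Cebpe and Nlrp12 stood at 165 and 554 CPM of UMIs in neutrophil-like cells and at 21.9 and 43.1 CPM in hepatocyte-like cells of the high-fat diet. The high-fat plus ethanol single-cell library lists 16626 barcodes, whose counts were not analysed here.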
